A study of Mus musculus with 5 samples.

How the data were processed

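RNA was measured by sequencing in 5 libraries of TER119-positive cells from mouse fetal liver at embryonic day 14.5, 3 from control and 2 from KO embryos, grouped by the titles and genotypes in the labels. Per the labels' protocols, cells were stained with a FITC antibody to TER119 and sorted on a FACS Aria, total RNA was purified on RNeasy columns, poly(A) RNA was selected on oligo(dT) beads, and libraries were made with the Ion Total RNA-Seq kit and read on an Ion Proton. Per the submitters' processing notes, the tools were cutadapt, STAR, Bowtie and HTSeq and the build was mm10; their versions and settings, including the use of strand and the treatment of reads that map to several places, are not given in the sources used here. The deposited table holds whole-number counts per gene for each library, not normalised by the authors. It lists 39179 Ensembl gene identifiers, of which 37607 matched a symbol in GENCODE release M21; the remaining 1572 held 0.365% to 0.388% of the counts. All 37 mitochondrial genes were listed at 0.

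Totals were 15366021, 13543392 and 14440363 counts in control replicates 1, 2 and 3 and 13187094 and 14986630 in KO replicates 1 and 2, with 18446 to 19037 genes counted at least once. The 10 most abundant genes took 8.34% to 10.3% of the counts. At these depths 1 CPM is 13.2 to 15.4 counts, so values under 1 CPM rest on few counts. The reads carry no molecular identifiers, so read counts are not counts of independent molecules.

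Differential expression was tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test (glmQLFit and glmQLFTest) on the counts as deposited. TMM library scaling gave factors of 0.970 to 1.03, genes were kept by filterByExpr with the group (13000 kept), the design held only the group, and Benjamini-Hochberg adjustment covered all genes kept, with a threshold of 0.05. With 3 residual degrees of freedom the spread was shared among genes, and the common biological coefficient of variation was 8.67%. CPM values in the text are edgeR's counts scaled to the TMM-adjusted library size. Standard errors of log2 fold changes were taken from the fold change and the F statistic. The same steps were tested on simulated counts drawn with the means, dispersions and library sizes of these 13000 genes in 5 simulations, with 200 genes changed in each. They recovered 47.6% of genes changed by 0.5 on the log2 scale, 82% of those changed by 1, 96.8% of those changed by 2 and 100% of those changed by 4, none with the wrong sign, and 10.1% of the calls were false, above the nominal rate.

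The contrast, the tests, 38 gene lists, the genes to name and the alternatives were fixed before the data were examined. The lists cover erythroid, cell cycle, stress, signalling, metabolic and cell type groups. The 36 with at least 3 members kept were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists. Of these, 6 lists passed upward and 5 downward; no list passed with an estimated correlation, where the smallest adjusted p was 0.65 and 1 list had an unadjusted p under 0.05, and 2 passed with fry. In 1 simulation in which the members of the p53 list were shifted by 0.5 on the log2 scale, that list was called and 0 of the others. Its genes were drawn independently of each other, so it does not test how correlation within lists affects the calls. The lists overlap in part, and Cdkn1a, Ccnd1, Ccnd2, Klf6 and Slc7a11 are among the genes that belong to more than 1.

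The genes named were the 3 CK2 subunits; the 10 largest increases and 10 largest decreases among genes past the threshold with at least 10 CPM in a group mean and both KO libraries beyond all controls, leaving out predicted genes, RIKEN clones and names marked as pseudogenes or related sequences; the 3 members of each list with the smallest p past the threshold, or up to 2 of the most abundant where none passed; and Gata1, Klf1, Epor, Kit, Alas2, Cdkn1a, Mdm2, Trp53 and Myc. Of the genes this rule picks, 2 are left out of the text. Ier3, Hbb-bh1, Tapbp, H2-K1, H2-T24, Clic1 and Notch3 are named outside this rule, after their values were seen, and so are the Y-linked genes, Slc40a1, Zbed5 and the neighbours of Rhbdf1. Coordinates and gene types come from GENCODE M21 on GRCm38, the assembly that mm10 names.

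The alternatives were RLE scaling, leaving out globin and mitochondrial genes, DESeq2 1.42.0, limma-voom, no filter on low counts, at least 5 CPM in 2 libraries, a 2-fold minimum, the replicate number as a block, each library left out in turn, and for the lists an estimated correlation, fry and a prior count of 0.5. Correlations of log2 CPM, principal components and chi-square tests over genes with at least 10 counts in a pair compared the libraries, the last against counting error alone and only to find a copied library. Odds around Csnk2b were compared by Fisher's exact test. No column of the table was left out.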

Results

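The libraries hold poly(A) RNA from erythroid cells of mouse fetal liver at embryonic day 14.5, sorted by flow cytometry for TER119, a surface marker of maturing erythroid cells. Fetal liver is the main site of red cell production at this stage. The 3 control libraries came from embryos with the Vav-Cre transgene, which drives Cre recombinase in blood-forming cells, and intact Csnk2b. The 2 KO libraries came from embryos with the same transgene and 2 floxed copies of Csnk2b, the gene for the regulatory beta subunit of the protein kinase CK2. Totals ranged from 13187094 to 15366021 counts per library, with 13187094 and 14986630 in KO replicates 1 and 2. The table listed 39179 genes, of which 13000 were tested.

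The 5 libraries parted by genotype. Log2 values of counts scaled to library size (CPM) correlated across genes at 0.995 to 0.996 between controls, at 0.991 between the KO libraries and at 0.983 to 0.986 between a control and a KO library. The first principal component, with 61.4% of the variance, separated the KO libraries from the controls, and the second, with 18.8%, separated the KO libraries from each other. Libraries of a group differed by more than counting error, as separate samples do, with a chi-square statistic per degree of freedom of 4.30 to 6.35 between controls and 17.7 between the KO libraries, so none is a copy of another. Counts of the Y-linked genes Eif2s3y, Ddx3y, Uty and Kdm5d were 454, 367, 174 and 147 in control replicate 3 and at most 2 in any other library. Control replicate 3 also held Xist, the RNA that coats the inactive X chromosome of female cells, at 547 CPM, beside 788 to 1026 CPM elsewhere. Only control replicate 3 thus held Xist together with more than 2 counts of a Y-linked gene, and why was not tested. The titles call each library an embryo with a number. They do not state whether it came from 1 embryo or from a pool, so the p-values measure the spread between these samples.

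The first comparison asked how far the targeted gene was reduced in the cells labelled KO. Csnk2b stood at 186, 186 and 169 CPM in control replicates 1, 2 and 3 and at 112 and 95.6 CPM in KO replicates 1 and 2. The KO mean was 104 CPM ± 11.3 (SD, n = 2) against 181 CPM ± 9.54 (SD, n = 3), so Csnk2b was 1.74-fold lower. Its log2 fold change was -0.80 ± 0.09 (SE), with an edgeR adjusted p of 0.0018. The catalytic subunit genes did not pass the test: Csnk2a1 had a log2 fold change of 0.16 ± 0.08 (edgeR adjusted p = 0.27) and Csnk2a2 one of -0.12 ± 0.09 (edgeR adjusted p = 0.44). As a list of 3 genes, the CK2 subunits had 1 member that fell, also when adjusted over the list alone, and a camera adjusted p of 0.24 (adjusted p = 0.808 with an estimated correlation). Csnk2b (ENSMUSG00000024387) lies on the minus strand of chromosome 17 from 35116196 to 35122053 in build mm10, within the major histocompatibility complex. The counts cover the whole gene, so reads from exons outside the deleted part may be included, and the labels do not name the floxed exons. Gpank1, on the opposite strand from 35121455 to 35124814, overlaps Csnk2b by 599 bp and fell by 0.88 ± 0.13 on the log2 scale (edgeR adjusted p = 0.0062). Whether the counting used strand is not given in the sources used here, so reads of the shared stretch cannot be assigned to either gene.

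**Figure D1:**
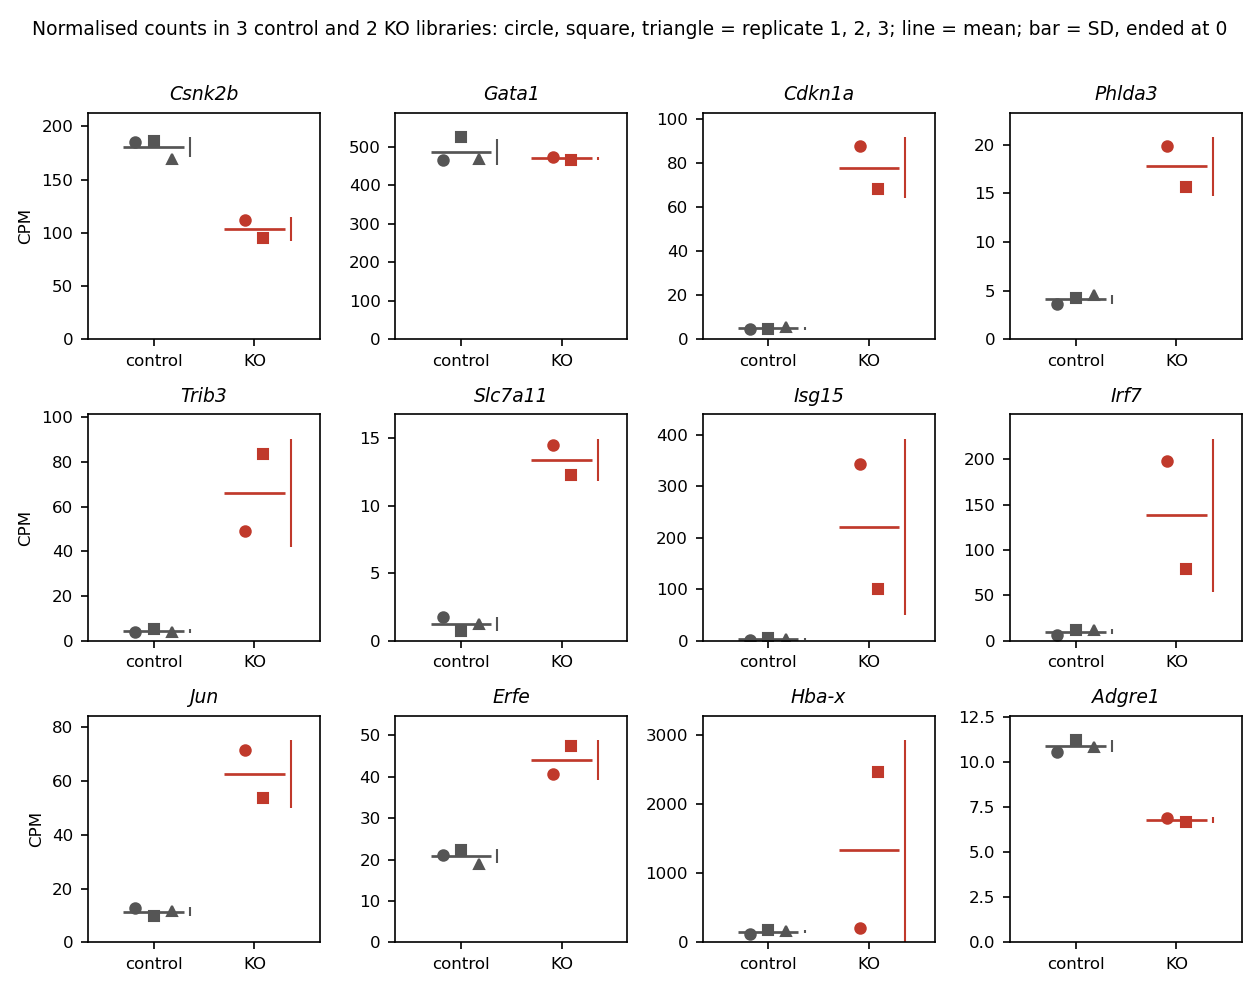
CPM of 12 genes in each library, on linear axes from 0, with the mean as a line and the SD as a bar. Csnk2b and Adgre1 were lower in both KO libraries than in all 3 controls, Gata1 overlapped between the groups, and Hba-x was 213 CPM in KO replicate 1 and 2462 CPM in KO replicate 2.

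The second comparison asked which genes differed between KO and control erythroid cells. In the KO cells, p53 targets such as Cdkn1a, interferon response genes, unfolded protein and integrated stress response genes and immediate early genes were higher as lists in camera. Macrophage markers were lower, and Gata1, Klf1 and Epor did not pass in edgeR. Of 36 lists tested 6 passed upward and 5 downward, and 0 passed with an estimated correlation, where the smallest adjusted p was 0.65. At an edgeR adjusted p below 0.05, 669 genes were higher and 238 lower in KO, 907 in all. Increases were larger than decreases. The median fold was 1.86 among genes that rose and 1.38 among genes that fell, and 290 genes rose by at least 2-fold while 3 fell by as much. In all 907 genes both KO libraries lay on the same side of all 3 controls, which passing the test with so few libraries nearly requires. That arrangement was found in 41.2% of the genes tested and expected by chance in 20%. The count depended on each library: 283, 241 and 400 genes were called without control replicate 1, 2 and 3. A fit without KO replicate 1 or 2 leaves a lone KO library, which is then assumed to vary like the controls. The KO libraries differed from each other by more than the controls did, so calls and p-values of those fits are not reliable. Without a filter on low counts 288 genes were called.

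**Figure D2:**
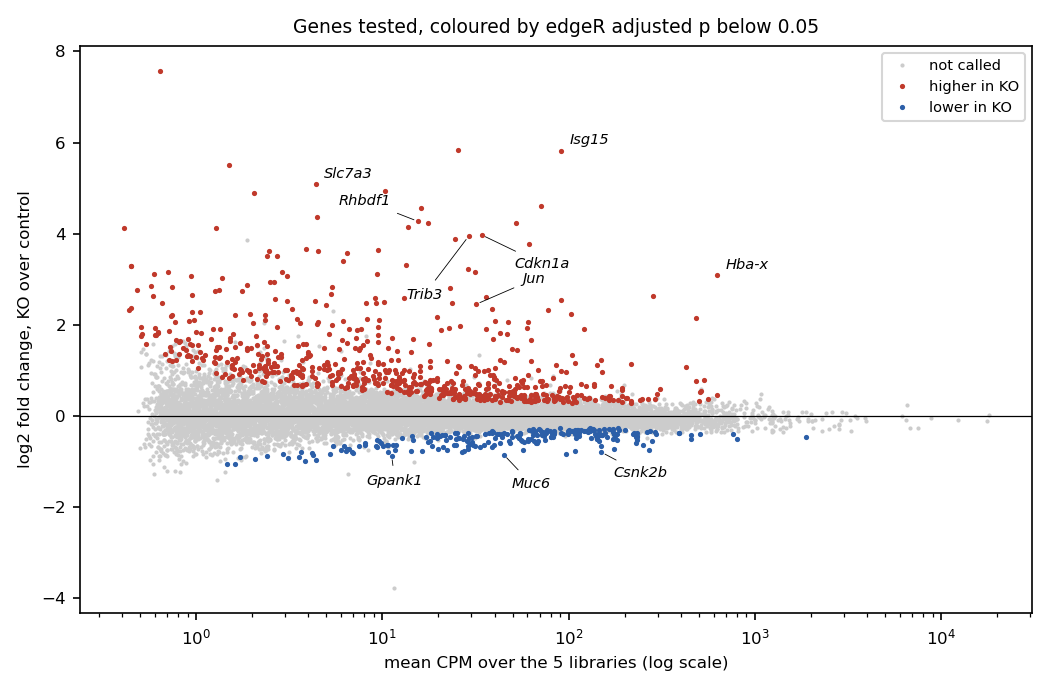
Log2 fold change of KO over control against mean CPM on a log axis, a point for each gene tested. The 669 genes higher in KO reach larger fold changes than the 238 lower, with Isg15 at 5.82, Slc7a3 at 5.09 and Muc6 at -0.86.

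With all 5 libraries, most of the measured genes that p53 is known to switch on rose. Of 27 p53 target genes measured, 18 rose and none fell, and adjusted over the list alone 21 rose and 1 fell. The number of members that rose was 13, 12 and 14 without control replicate 1, 2 and 3. Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21, went from 4.94 CPM ± 0.58 (SD, n = 3) to 77.8 CPM ± 13.9 (SD, n = 2), a 15.7-fold rise with an edgeR adjusted p of 2.1e-06. Phlda3, an inhibitor of AKT signalling, rose 4.30-fold (edgeR adjusted p = 0.00026) and Zmat3, an RNA-binding protein gene, 3.86-fold (edgeR adjusted p = 0.00061). Mdm2, whose product degrades p53, rose 1.27-fold (edgeR adjusted p = 0.044). Trp53 itself had a log2 fold change of 0.08 ± 0.09 (edgeR adjusted p = 0.63). The list's median log2 fold change was 0.67, with a camera adjusted p of 2.3e-10, which became an adjusted p of 0.65 with an estimated correlation. Cdkn1a, Phlda3 and Zmat3 passed in each fit that left out a library, whereas Mdm2 missed the threshold without any 1 control or KO replicate 1 (adjusted p up to 0.17) and with RLE scaling (0.053).

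Among 14 CDK inhibitors and cyclins, Cdkn1a, Ccnd2 and Ccnd1 rose, and adjusted over the list alone 3 rose and 1 fell. Ccnd2, a D-type cyclin, went from 101 CPM ± 7.56 (SD, n = 3) to 158 CPM ± 12.9 (SD, n = 2), and Ccnd1 from 15.0 CPM ± 2.05 to 23.0 CPM ± 2.20 (SD, n = 3 and 2). As a group they had a camera adjusted p of 0.21 (adjusted p = 0.808 with an estimated correlation). DNA replication and G1/S genes were slightly lower together: 29 of 30 had a fold change below 1 and their median log2 fold change was -0.14, with a camera adjusted p of 1.4e-05 (adjusted p = 0.655 with an estimated correlation). Tyms, for thymidylate synthase, was the 1 member of that list to pass singly with all 5 libraries, with a decrease of 0.30 ± 0.07 on the log2 scale (edgeR adjusted p = 0.04), and adjusted over the list alone 0 fell. Among 25 mitosis and G2/M genes none passed the test in edgeR, and the list had a median of -0.09 and a camera adjusted p of 0.051. Mki67, the proliferation marker, was at 7261 CPM ± 209 (SD, n = 3) and 6027 CPM ± 1412 (SD, n = 2), and Top2a, the mitotic topoisomerase gene, had a log2 fold change of -0.07 ± 0.09. In the DNA damage response list, Trp53bp1, a double-strand break protein gene, fell by 0.51 ± 0.08 on the log2 scale (edgeR adjusted p = 0.009) as the 1 member of 24 to pass, also adjusted over the list alone. Tyms missed the threshold without any 1 control or KO replicate 2 (adjusted p up to 0.15), Ccnd1 without control replicate 2 or 3 or KO replicate 2 (up to 0.11), and Trp53bp1 without control replicate 1 or 2 (up to 0.058). Without KO replicate 1 the median log2 fold changes were -0.20 for DNA replication, -0.21 for mitosis, -0.085 for DNA damage and -0.053 for CDK inhibitors and cyclins. Without KO replicate 2 they were -0.13, -0.015, -0.046 and 0.096. The DNA damage list and the list of 19 apoptosis regulators had camera adjusted p-values of 0.16 and 0.19.

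Of 21 interferon-stimulated genes measured, 15 rose and none fell, and adjusted over the list alone 16 rose. Isg15, a ubiquitin-like modifier, went from 3.98 CPM ± 1.79 (SD, n = 3) to 222 CPM ± 171 (SD, n = 2), a 56.6-fold rise (edgeR adjusted p = 0.00066). Irf7, a transcription factor of the interferon pathway, rose 13.6-fold (edgeR adjusted p = 0.00093), and Bst2, which tethers budding virus, rose 4.50-fold (edgeR adjusted p = 1.7e-05). Isg15, Ifit1, Oas1a, Rsad2, Oas3, Xaf1, Oasl2 and Usp18 were 8 of the 10 largest rises under the naming rule with all 5 libraries, with log2 fold changes from 4.23 for Usp18 to 5.83 for Ifit1. Most of these were higher in KO replicate 1 than in KO replicate 2, as with Isg15 at 343 and 101 CPM and Rsad2 at 312 and 22.8 CPM, whereas Bst2 was at 33.7 and 39.6 CPM. The list's median log2 fold change was 2.24, with a camera adjusted p of 1.9e-09, which became an adjusted p of 0.794 with an estimated correlation. The number of members that rose was 9 without control replicate 1 and 9 without control replicate 2, fits in which Oas3 and Rsad2 missed the threshold (adjusted p up to 0.085 and 0.10), and Xaf1 missed it without any 1 control (up to 0.15). With limma-voom Oas3, Rsad2 and Xaf1 also missed it (0.073, 0.11 and 0.14). The median was 1.62 without KO replicate 1 and 2.87 without KO replicate 2, and without KO replicate 1 Isg15 was at 4.67, Ifit1 at 4.16, Irf7 at 2.94, Oas1a at 3.77, Oasl2 at 2.80, Usp18 at 3.27, Oas3 at 2.38, Rsad2 at 1.71 and Xaf1 at 1.51. In that fit Trib3, at 4.25, exceeded each of these but Isg15, and Slc7a3 and Rhbdf1 were at no less than 4.88 and 4.20 in any fit that left out a library, so the order depends on KO replicate 1. Oas family genes are similar in sequence, and reads may be divided among them.

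Genes of the unfolded protein and integrated stress response also rose in part. Of 29 measured, 8 rose and none fell, and adjusted over the list alone 11 rose. Trib3, a pseudokinase induced by amino acid shortage and endoplasmic reticulum stress, went from 4.33 CPM ± 0.74 (SD, n = 3) to 66.2 CPM ± 24.2 (SD, n = 2), a 15.4-fold rise (edgeR adjusted p = 4.9e-05). Slc7a11, which imports cystine, rose 10.5-fold (edgeR adjusted p = 0.00013) and Atf5, a transcription factor of the same response, 6.07-fold (edgeR adjusted p = 0.0013). Slc7a3, a transporter of cationic amino acids, is not a member of this list. It rose 34.1-fold from 0.31 CPM ± 0.07 (SD, n = 3) to 10.5 CPM ± 1.96 (SD, n = 2), with an edgeR adjusted p of 1.7e-05. The stress list had a median log2 fold change of 0.14 and a mean of 0.60, with a camera adjusted p of 0.0025 (adjusted p = 0.655 with an estimated correlation). Without control replicate 1 the number of members that rose was 5, and without KO replicate 2 the log2 fold change of Atf5 went from 2.60 to 1.97. The median of the stress list was 0.18 without KO replicate 1 and 0.068 without KO replicate 2. That of the NRF2 targets was 0.017 and -0.046. Srxn1, an antioxidant enzyme gene, rose 1.58-fold (edgeR adjusted p = 0.0016) and with Slc7a11 made up the 2 of 19 oxidative stress and NRF2 targets that rose; adjusted over the list alone 2 rose and 1 fell, and the camera adjusted p was 0.90, with a median of -0.01 and a mean of 0.19. Among 17 cytosolic chaperones, the neighbouring heat shock genes Hspa1a and Hspa1b rose, by 4.20-fold and 3.14-fold. Both lie within 5 Mb of Csnk2b and are counted among the rises there. Adjusted over the list alone 2 rose and 1 fell, with a camera adjusted p of 0.74. Hspa1a and Hspa1b are near-identical copies whose reads cannot be assigned with certainty, and Hspa1a missed the threshold without any 1 control (adjusted p up to 0.12) and with limma-voom (0.07), its log2 fold change going from 2.07 to 0.91 without KO replicate 1, and Hspa1b missed it without control replicate 2 (0.059). The median of the chaperone list was 0.082 without KO replicate 1 and -0.061 without KO replicate 2.

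Of 15 immediate early genes measured, 7 rose and 1 fell, and adjusted over the list alone 9 rose and 1 fell. The member that fell, Ier3, named after its values were seen, missed the threshold without any 1 control or KO replicate 2 (adjusted p up to 0.16). Jun, a subunit of the AP-1 transcription factor, went from 11.4 CPM ± 1.59 (SD, n = 3) to 62.5 CPM ± 12.5 (SD, n = 2), a 5.45-fold rise (edgeR adjusted p = 4.9e-05). Jund rose 2.01-fold (edgeR adjusted p = 0.0011) and Klf6 1.97-fold (edgeR adjusted p = 0.0032). The list's median was 0.69 and its camera adjusted p was 0.0029 (adjusted p = 0.794 with an estimated correlation), and without KO replicate 1 the camera adjusted p was 0.16. Klf6 was also 1 of 3 FOXO and PI3K-AKT targets of 16 that rose, with Txnip and Tsc22d3. In that list 4 rose when adjusted over the list alone, and its camera adjusted p was 0.077 (adjusted p = 0.808 with an estimated correlation). Txnip missed the threshold without any 1 control (adjusted p up to 0.11) and Tsc22d3 without any 1 control or KO replicate 2 (up to 0.079) and with DESeq2 (0.054). In the FOXO list 1 member rose without any 1 control. Without KO replicate 1 the FOXO median was 0.052 and the immediate early median 0.61. Without KO replicate 2 they were 0.30 and 0.74.

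Of 14 targets of erythropoietin and STAT5 signalling measured, 5 rose, none fell and 9 did not pass, and adjusted over the list alone 7 rose and 1 fell. Erfe, the erythroid hormone erythroferrone that lowers hepcidin, went from 20.8 CPM ± 1.68 (SD, n = 3) to 44.0 CPM ± 4.85 (SD, n = 2), a 2.12-fold rise (edgeR adjusted p = 0.00093). Ccnd2 and Serpina3g were the next by p, with log2 fold changes of 0.64 ± 0.09 and 1.83 ± 0.33, the latter at 0.30 and 1.11 CPM in the group means and missing the threshold without control replicate 1 or 2 (adjusted p up to 0.065) and with DESeq2 (0.16). The number of members that rose was 2 without control replicate 1 or 2 and 3 without control replicate 3 or KO replicate 2. The list had a median log2 fold change of 0.31 and a camera adjusted p of 0.0082 (adjusted p = 0.655 with an estimated correlation). Epor, the receptor, had a log2 fold change of -0.04 ± 0.09 (edgeR adjusted p = 0.83). The NF-kB targets had no member past the threshold among 11 in edgeR on either adjustment, with Nfkb1 at 0.15 ± 0.08 and Nfkb2 at 0.16 ± 0.12 on the log2 scale. Their median was 0.21 and their camera adjusted p 0.039 (adjusted p = 0.655 with an estimated correlation), and the list missed the threshold without control replicate 2 (0.067), without KO replicate 1 (0.16) and with a stricter filter (0.24). The NF-kB median was 0.31 without KO replicate 1 and 0.40 without KO replicate 2, and the EPO-STAT5 median was 0.27 and 0.30.

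The main erythroid regulators did not pass the test singly. Gata1, the main erythroid transcription factor, was at 486 CPM ± 34.1 (SD, n = 3) and 469 CPM ± 3.86 (SD, n = 2), with a log2 fold change of -0.05 ± 0.08 (edgeR adjusted p = 0.76). Klf1 had one of -0.21 ± 0.10 (edgeR adjusted p = 0.23), Alas2, the first enzyme of erythroid heme synthesis, one of -0.22 ± 0.11 (edgeR adjusted p = 0.28), Kit, the stem cell factor receptor, one of -0.30 ± 0.08 (edgeR adjusted p = 0.059) and Myc one of 0.13 ± 0.10 (edgeR adjusted p = 0.49). As lists, however, several erythroid groups were lower by a small amount. The 24 membrane and cytoskeleton genes, among them Slc4a1 at -0.12 ± 0.14 and Sptb at -0.01 ± 0.12, had no member past the threshold on either adjustment, a median of -0.18 and a camera adjusted p of 6.5e-05 (adjusted p = 0.808 with an estimated correlation). The 19 erythroid transcription factors and receptors had none either, with E2f2 at -0.06 ± 0.11 and Tal1 at 0.00 ± 0.09. Their median was -0.08 and their camera adjusted p 0.011 (adjusted p = 0.808 with an estimated correlation). Of 25 heme synthesis and iron handling genes, Tmem14c, a mitochondrial porphyrin transporter gene, and Steap3, a ferrireductase gene, fell by 0.40 ± 0.07 and 0.35 ± 0.09 on the log2 scale, also adjusted over the list alone. That list had a camera adjusted p of 0.0029 (adjusted p = 0.808 with an estimated correlation). Without KO replicate 2 these 3 lists missed the threshold (0.078 for membrane, 0.15 for transcription factors and 0.078 for heme), the last 2 also without control replicate 2 (0.072 and 0.053). Without KO replicate 1 the medians were -0.34 for membrane, -0.22 for transcription factors, -0.17 for heme and -0.21 for late erythroid genes. Without KO replicate 2 they were -0.059, -0.093, -0.077 and 0.025. Steap3 missed the threshold without any 1 control or KO replicate 2 (adjusted p up to 0.15) and Tmem14c without any 1 control (up to 0.088). Of 23 late erythroid maturation genes Xpo7, a nuclear exporter gene, fell by 0.48 ± 0.12 (edgeR adjusted p = 0.047) and adjusted over the list alone 0 fell, with a camera adjusted p of 0.12. Xpo7 missed the threshold without any 1 control or KO replicate 2 (adjusted p up to 0.17) and with RLE scaling (0.051). The 17 stem and early progenitor markers had none past the threshold in edgeR on either adjustment and a camera adjusted p of 0.74, with Myb at -0.16 ± 0.09. The median of these markers was 0.18 without KO replicate 1 and -0.023 without KO replicate 2.

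Globin genes took 4.21% to 5.31% of the counts per library. Adult globins had no member of 4 past the threshold on either adjustment and a camera adjusted p of 0.75: Hbb-bs was at 17893 CPM ± 2106 (SD, n = 3) and 18132 CPM ± 2920 (SD, n = 2), and Hba-a1 at 12588 CPM ± 3298 and 11702 CPM ± 3914 (SD, n = 3 and 2). Hba-a1 has a near-identical copy and Hbb-bs a close one, so their reads may be divided. The embryonic globins Hba-x and Hbb-y rose, 2 of 3 genes measured, mainly in 1 library. Hba-x was at 213 and 2462 CPM in KO replicates 1 and 2 against 157 CPM ± 25.9 (SD, n = 3), with an edgeR adjusted p of 0.036, and Hbb-y at 296 and 1495 CPM against 203 CPM ± 64.6, with an edgeR adjusted p of 0.042. Adjusted over the list alone, 2 rose and 1 fell, and the camera adjusted p was 0.75. The third member, Hbb-bh1, named after its values were seen, had a log2 fold change of -0.49 ± 0.14 (edgeR adjusted p = 0.067), which passed without KO replicate 2 at -0.71 (0.018) and with DESeq2 at -0.50 (0.0048). Without KO replicate 2 the log2 fold change of Hba-x went from 3.09 to 0.43 and that of Hbb-y from 2.14 to 0.54, and neither passed; both also missed the threshold without any 1 control, with DESeq2 (0.071 and 0.089) and with limma-voom (0.13 and 0.094). The labels give day 14.5 for every library, and whether KO replicate 2 came from a less mature embryo was not tested, which bears on the embryonic globin, glycolysis and erythroid list values.

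Markers of liver macrophages, the cells around which erythroblasts mature, were lower in the KO sorts. Of 17 measured, 6 fell and none rose, and adjusted over the list alone 12 fell. Adgre1, which encodes the F4/80 antigen, went from 10.9 CPM ± 0.33 (SD, n = 3) to 6.80 CPM ± 0.17 (SD, n = 2), 1.60-fold lower (edgeR adjusted p = 0.016). Cd5l, a protein secreted by macrophages, fell by 0.78 ± 0.14 (edgeR adjusted p = 0.012) and Marco, a scavenger receptor gene, by 0.79 ± 0.15 on the log2 scale (edgeR adjusted p = 0.016). The list's median log2 fold change was -0.40, with a camera adjusted p of 1.9e-09, which became an adjusted p of 0.655 with an estimated correlation. The number of members that fell was 2, 0 and 1 without control replicate 1, 2 and 3 and 3 without KO replicate 2. Adgre1 missed the threshold without any 1 control (adjusted p up to 0.072), Marco also without KO replicate 2 (up to 0.073), and Cd5l without control replicate 2 (0.065).

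Markers of other cell types that a fetal liver sort could hold did not pass as lists. Camera adjusted p-values were 0.83 for 18 hepatocyte markers, 0.24 for 14 granulocyte and monocyte markers, 0.97 for 16 megakaryocyte and platelet markers, 0.24 for 4 mast cell and basophil markers, 0.14 for 7 lymphoid markers and 0.98 for 12 endothelial and stromal markers. No hepatocyte, granulocyte, megakaryocyte or lymphoid marker passed in edgeR on either adjustment with all 5 libraries. Without KO replicate 1 the median was 0.12 for megakaryocyte and -0.48 for mast cell markers, and without KO replicate 2 -0.14 and -0.30. Mpo, the granulocyte peroxidase, was at 473 CPM ± 83.5 (SD, n = 3) and 488 CPM ± 44.7 (SD, n = 2), and S100a9 at 41.1 CPM ± 7.64 and 39.3 CPM ± 10.6. Log2 fold changes were 0.09 ± 0.16 for Afp and -0.04 ± 0.18 for Alb, both hepatocyte genes. In the platelet list they were -0.04 ± 0.07 for Rap1b and 0.04 ± 0.16 for Thbs1, and in the lymphoid list -0.07 ± 0.29 for Nkg7 and -0.77 ± 0.37 for Rag1. Adjusted over the list alone, 1 mast cell marker rose and 1 fell, with Hdc at 0.39 ± 0.14 and Il1rl1 at -0.38 ± 0.11 on the log2 scale. The collagen genes Col1a1 and Col1a2 rose 4.14-fold and 2.16-fold (3 rose and 1 fell adjusted over the list alone), mainly in KO replicate 2 with 12.1 CPM of Col1a1 against 4.38 CPM in KO replicate 1. Col1a1 and Col1a2 missed the threshold without any 1 control (adjusted p up to 0.09 and 0.19), Col1a2 also without KO replicate 2 and with limma-voom (0.054). Without KO replicate 2 the log2 fold change of Col1a1 went from 2.05 to 1.11. The megakaryocyte list had a median of 0.05 while the test pointed down, and the endothelial and stromal list a median of -0.02 and a mean of 0.31.

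Of the metabolic and growth lists, glycolysis had 3 genes that rose among 17 and, adjusted over the list alone, 6 that rose and 2 that fell. Pfkp rose 2.29-fold (edgeR adjusted p = 0.0033), Pkm 2.18-fold (edgeR adjusted p = 0.027) and Aldoa 1.70-fold (edgeR adjusted p = 0.024), with Pkm at 202 and 437 CPM in KO replicates 1 and 2, and the list had a camera adjusted p of 0.14. Pkm and Aldoa missed the threshold without any 1 control (adjusted p up to 0.13 and 0.11), which left 1 member that rose. Pkm also missed it with DESeq2 (0.06), and its log2 fold change went from 1.13 to 0.46 without KO replicate 2. The glycolysis median was 0.35 without KO replicate 1 and 0.072 without KO replicate 2. Of 81 cytosolic ribosomal protein genes Rpl13a rose 1.43-fold, and of 28 ribosome biogenesis genes Rrp9 rose 1.45-fold, and adjusted over the list alone 0 rose in either. The camera adjusted p was 0.14 for the ribosomal proteins and 0.069 for ribosome biogenesis, and both lists passed with a stricter filter, at 0.019 and 0.036. Rpl13a and Rrp9 missed the threshold without any 1 control or KO replicate 2 (adjusted p up to 0.17 and 0.16) and with limma-voom (0.056 and 0.055). When KO replicate 1 was left out, medians were 0.23 for ribosomal proteins, 0.18 for ribosome biogenesis and 0.083 for cholesterol synthesis. They were 0.081 for OXPHOS and 0.073 for Wnt and Hedgehog targets. When KO replicate 2 was left out, these medians were -0.011, -0.017, -0.047, -0.020 and 0.036 in the same order. The histone median was -0.10 without KO replicate 1 and 0.22 without KO replicate 2. The histone list had 1 of 13 genes that rose, H1f0, by 1.47-fold (edgeR adjusted p = 0.0041), also adjusted over the list alone, and a camera adjusted p of 0.17. None of 22 nuclear OXPHOS genes or 19 cholesterol synthesis genes passed in edgeR on either adjustment, and the camera adjusted p-values were 0.75 and 0.91. Atp5a1 was at 0.02 ± 0.10, Atp5b at 0.07 ± 0.10 and Srebf2 at -0.04 ± 0.07 on the log2 scale. Of 6 Wnt and Hedgehog targets Ccnd1 rose, also adjusted over the list alone, with a camera adjusted p of 0.75. Several of these lists passed in camera when 1 library was left out. Without KO replicate 1 the mitosis, late erythroid, ribosome biogenesis, ribosomal protein, glycolysis, lymphoid, granulocyte, embryonic globin and DNA damage lists passed. In that fit the lone KO library is assumed to vary like the controls. Without control replicate 1 the adjusted p was 0.043 for late erythroid maturation, and without control replicate 2 0.0078 for ribosomal proteins and 0.006 for granulocyte markers. Without control replicate 3 it was 0.046 for mitosis, 0.038 for hepatocyte markers and 0.038 for FOXO targets, and without KO replicate 2 0.0015 for FOXO targets. For all lists that did not pass with the preset correlation, the adjusted p was 0.794 to 0.991 with an estimated correlation. The mitochondrially encoded list could not be tested because all 37 mitochondrial genes were listed at 0 in every library, and of the sex-linked list only Xist was abundant enough to test.

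**Figure D3:**
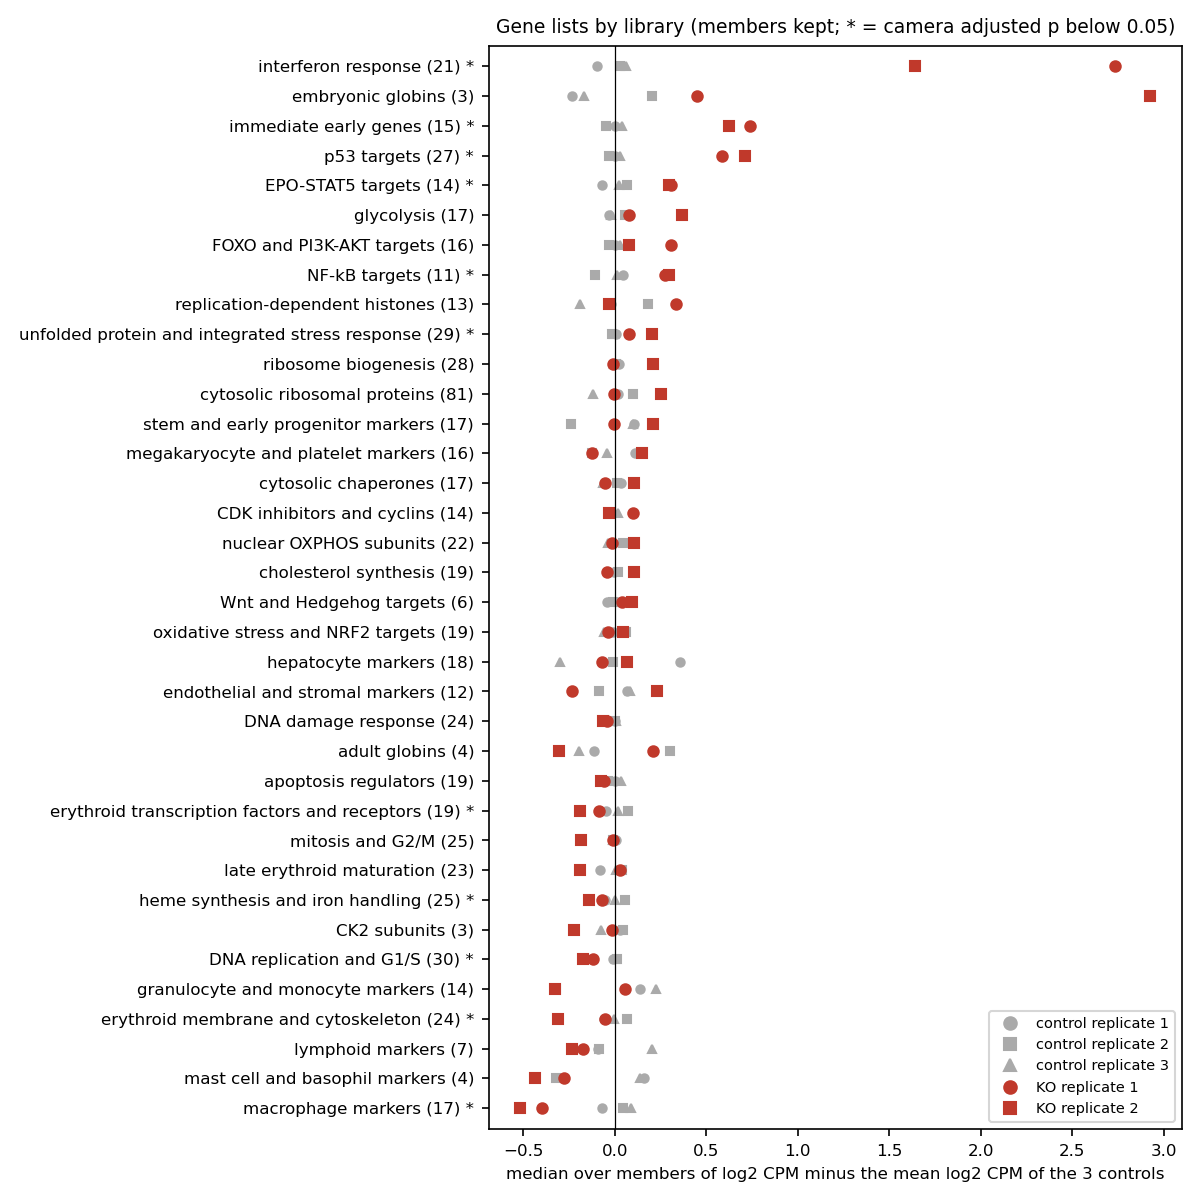
Median over the members of each gene list of the log2 CPM minus the mean of the 3 controls, for each library, with the number of members tested and an asterisk for a camera adjusted p below 0.05. Both KO libraries lie to the right of the controls for the p53 and interferon lists and to the left for the macrophage list, and KO replicate 2 is at 2.93 for the embryonic globins.

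Outside the lists, the smallest adjusted p of all genes was that of Rhbdf1, an inactive rhomboid protein gene. It went from 1.86 CPM ± 0.17 (SD, n = 3) to 36.0 CPM ± 0.20 (SD, n = 2), a 19.3-fold rise (edgeR adjusted p = 1.2e-06). Rhbdf1 lies on chromosome 11 from 32209585 to 32222300, beside the alpha-globin genes. The 10 largest decreases under the naming rule were Gpank1, Muc6, Tns1, Stard10, Csnk2b, Cd36, Trim2, Cd5l, Mocs1 and Sh3tc2, with log2 fold changes from -0.88 for Gpank1 to -0.75 for Sh3tc2. Muc6, a mucin gene, went from 54.6 CPM ± 3.00 (SD, n = 3) to 30.2 CPM ± 4.58 (SD, n = 2), and Cd36, a fatty acid transporter gene, from 32.9 CPM ± 2.35 to 19.1 CPM ± 1.90 (SD, n = 3 and 2). Tns1 encodes an actin-binding protein of focal adhesions and Stard10 a lipid transfer protein. Trim2 missed the threshold without control replicate 1 or 2 (adjusted p up to 0.052) and Cd5l without control replicate 2 (0.065), and the others passed in each fit that left out a library.

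Around Csnk2b on chromosome 17, genes passed the test more often than elsewhere, a count made after the calls were seen. Of 164 other genes tested within 5 Mb, 29 rose and 2 fell, which is 18.9%, against 6.82% of the 12835 genes farther away (Fisher's exact p = 2.9e-07, two-sided, odds ratio 3.19 with a 95% interval of 2.07 to 4.77). The antigen presentation genes Tapbp, H2-K1 and H2-T24 were among them, with log2 fold changes of 1.22, 1.21 and 2.54, and so were Clic1 at 0.96 and Notch3 at 4.88 (3.75 without KO replicate 2). These 5 genes were chosen after their values were seen, and reads of the H2 family may be divided among its members. Cdkn1a lies on the same chromosome from 29090976 to 29100727, outside this window, and whether it shares a cause with the genes inside was not tested. Genes are not independent replicates, and neighbours can be regulated together.

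**Figure D4:**
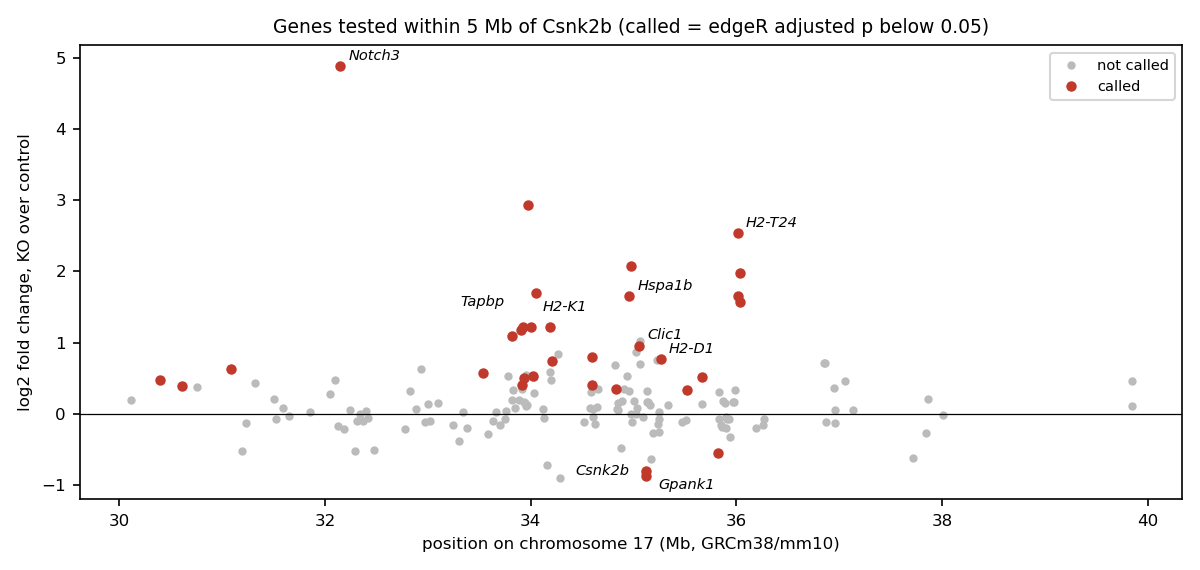
Log2 fold change of KO over control for the genes tested within 5 Mb of Csnk2b, by position on chromosome 17 in Mb. Of these genes 29 rose, mostly between Notch3 and H2-T24, and Csnk2b, Gpank1 and Ier3 fell.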

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

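Csnk2b was lower in KO and past the threshold with each other scaling, filter and tool and with each library left out in turn, the last with log2 fold changes of -0.94 to -0.70, but its decrease of 1.74-fold is below the 2-fold minimum. The count of changed genes, 907, was 917 with RLE scaling, 917 without globin and mitochondrial genes, 832 with DESeq2, 842 with limma-voom and 717 with a stricter filter. Of the 907 genes, 891 were called again with RLE scaling and 674 with DESeq2, and 0 changed sign in any setting. A 2-fold minimum left 293 genes (290 higher, 3 lower), as its construction requires. Without a filter on low counts, with 21077 genes tested, 288 were called (235 higher, 53 lower), and the cause was not tested. With each library left out in turn, 241 to 2956 were called (210 to 1709 higher, 31 to 1247 lower). In the fits without a KO replicate the lone KO library is assumed to vary like the controls. The depths of 13.2 to 15.4 counts per CPM limit what can be seen of genes under 1 CPM.

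Of the genes picked by the naming rule or named afterwards, other than Csnk2b, 98 of 100 kept direction and side of the threshold with RLE scaling, 94 of 95 without globin and mitochondrial genes, 94 of 100 with DESeq2, 91 of 100 with limma-voom, 76 of 100 without a filter and 93 of 94 with a stricter filter. None reversed in these 6 settings; 18 genes that did not pass reversed in at least 1 fit that left out a library, and the cause was not tested. Their ranges were Afp -0.090 to 0.27, Alb -0.20 to 0.17, Atp5a1 -0.096 to 0.11, Atp5b -0.021 to 0.13, E2f2 -0.23 to 0.058, Epor -0.098 to 0.011, Gata1 -0.082 to 0.0086, Hba-a1 -0.52 to 0.20, Hbb-bs -0.18 to 0.17, Mpo -0.087 to 0.16, Myc -0.078 to 0.28, Nkg7 -0.31 to 0.18, S100a9 -0.40 to 0.18, Sptb -0.12 to 0.072, Srebf2 -0.076 to 0.0033, Tal1 -0.081 to 0.052, Thbs1 -0.25 to 0.25 and Xist -0.18 to 0.22.

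Of the 11 lists past the threshold, 0 passed with an estimated correlation, none higher and none lower. The estimates were 0.76 for membrane, 0.64 for interferon, 0.45 for erythroid transcription factors and 0.40 for heme, far above the preset 0.01. They were 0.065 for p53, 0.026 for the stress response and -0.026 for NF-kB, which also lost their call. A higher correlation cannot account for the loss of the NF-kB list. Its estimate lies below the preset 0.01, yet its unadjusted camera p went from 0.012 to 0.078. For the other lists, how much of the loss the correlation accounts for was not tested. The medians, which the test does not alter, were 2.24 for interferon, 0.69 for immediate early genes, 0.67 for p53, 0.31 for EPO-STAT5, 0.21 for NF-kB, 0.14 for the stress response, -0.081 for erythroid transcription factors, -0.11 for heme, -0.14 for DNA replication, -0.18 for membrane and -0.40 for macrophage markers. With fry 2 passed, p53 and the stress response, both higher and 0 lower, and the megakaryocyte list (median 0.049) turned. With a prior count of 0.5 all 36 kept their side. The mitosis list passed without globin and mitochondrial genes (-0.10) and without a filter (-0.088), where FOXO (0.23) and lymphoid (-0.20) lists also passed and the megakaryocyte (0.12) and endothelial (-0.028) tests turned. With a stricter filter ribosomal proteins (0.12) and ribosome biogenesis (0.11) passed, NF-kB (0.15) did not, and the hepatocyte (-0.013), megakaryocyte (0.050) and endothelial (-0.011) tests turned. The cause was not tested.

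With each library left out, 9 to 18 lists passed, 2 to 10 of them lower. Medians of lists whose call or direction moved ranged as follows, and the cause was not tested: DNA damage -0.085 to -0.036, FOXO 0.052 to 0.30, NF-kB 0.22 to 0.40, Wnt and Hedgehog 0.0016 to 0.073, adult globins -0.35 to 0.18, cholesterol -0.047 to 0.083, chaperones -0.061 to 0.082, ribosomal proteins -0.011 to 0.23, embryonic globins 0.43 to 3.04, endothelial -0.25 to 0.20, membrane -0.34 to -0.059, erythroid transcription factors -0.22 to -0.069, glycolysis 0.072 to 0.35, granulocyte -0.40 to 0.0020, heme -0.17 to -0.077, hepatocyte -0.14 to 0.18, immediate early 0.61 to 0.74, late erythroid -0.21 to 0.025, lymphoid -0.39 to 0.010, megakaryocyte -0.14 to 0.14, mitosis -0.21 to -0.015, OXPHOS -0.020 to 0.081, NRF2 -0.046 to 0.055, ribosome biogenesis -0.017 to 0.18 and stem -0.023 to 0.18.

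Control and KO libraries share only replicate numbers, in 2 pairs, whose residual correlations were 0.0016 and 0.042. With the replicate block 873 genes were called (702 higher, 171 lower), 701 of them among the 907. Afp (-0.034), Nkg7 (0.16), S100a9 (0.016), Tal1 (0.0025) and Xist (-0.19) reversed with it, as did the tests of the NRF2 (-0.038) and cholesterol (0.012) lists, while the mitosis (-0.092), FOXO (0.26) and hepatocyte (-0.14) lists and the genes Hdc (0.49) and Hbb-bh1 (-0.58) passed, and the cause was not tested.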

Other observations

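Some values stand apart from the comparisons. Zbed5, a gene with a transposon-derived domain chosen after its values were seen, was at 52.9 CPM in control replicate 2 and at 0.97 to 1.36 CPM in the other 4 libraries. Of the neighbours of Rhbdf1, also chosen afterwards, Snrnp25 had a log2 fold change of 0.18 ± 0.10, Nprl3 one of -0.15 ± 0.08 and Mpg one of 0.28 ± 0.09. None of these 3 passed in edgeR, while Hba-x, also within 200 kb, did at 3.09 ± 0.72 (edgeR adjusted p = 0.036). Hba-x was at 213 and 2462 CPM in KO replicates 1 and 2, whereas Rhbdf1 was at 36.1 and 35.8 CPM. Without KO replicate 2 the log2 fold change of Hba-x was 0.43.

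The tests below were chosen after the result was seen, except the one of macrophage markers against random lists of the same control level. The first pattern is the rise of interferon response genes such as Isg15, Ifit1 and Irf7 in KO cells. A larger share of leukocytes in the KO sorts would raise leukocyte markers. For macrophages the markers argue against it, with medians of -0.40 and -0.52 in KO replicates 1 and 2 and -0.069 to 0.090 in the controls. The pooled median log2 change was -0.29 (95% bootstrap interval over genes -0.40 to -0.18, 38 macrophage, granulocyte and lymphoid genes). That pool holds the 17 macrophage markers already seen to be lower. By list it was -0.40 for macrophage, -0.18 for lymphoid and -0.14 for granulocyte markers. The last 2 lists did not pass, and granulocyte markers were at 0.053 in KO replicate 1, so a larger share of those cells stays open. Whether leukocytes that the sorts did hold carried the interferon transcripts was not tested and stays open. A single KO library is argued against too, since 15 of 21 members rose without KO replicate 1 and 18 of 23 without KO replicate 2. The genotype and exposure of the KO embryos to interferon from other cells stay open, and no test here tells them apart.

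The second pattern is the gathering of changed genes around Csnk2b, among them Tapbp, H2-K1, Clic1 and Notch3. Interferon genes that passed were higher in KO replicate 1 than in KO replicate 2 by a median log2 ratio of 1.58 (95% bootstrap interval 1.32 to 2.10). The 31 genes within 5 Mb had one of -0.077 (-0.19 to 0.20). Some of these 31 changed little, as Pbx2 at 0.40 and Stk19 at 0.34, which limits the ratio they can reach. The interferon gene Bst2 was itself at 33.7 and 39.6 CPM in KO replicates 1 and 2. The ratios therefore cannot decide whether the interferon response alone explains the gathering. With antigen presentation and interferon genes left out, 22 of 148 genes there passed (20 higher and 2 lower, Gpank1 and Ier3). That is 14.9% against 6.71% elsewhere, an odds ratio of 2.43 (95% interval 1.46 to 3.87). A share as high as 14.9% was reached by 2.43% of 8255 windows of 5 Mb around other genes. Each of these windows held at least 50 genes, and they overlap, so they are not independent. A chromosome segment from another strain, carried along with the floxed allele, is a candidate explanation that these values leave open. Effects of the altered locus on its neighbours were not tested.

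The third pattern is the lower level of macrophage markers such as Adgre1, Cd5l and Marco in the KO sorts. Markers of the other non-erythroid types had a pooled median log2 change of -0.064 (95% bootstrap interval -0.094 to -0.00066, 71 genes) and the macrophage markers one of -0.40 (-0.78 to -0.29). These intervals resample genes, which move together within a list (estimated correlation 0.86 for granulocyte and 0.55 for hepatocyte markers). They hold no spread between embryos, so they cannot exclude a lower share of every other cell type. Mast cell, lymphoid and granulocyte markers had medians of -0.38, -0.18 and -0.14, and the last 2 were at -0.39 and -0.40 without KO replicate 1, so a lower share of these leukocytes too stays open. Fewer counts for genes of low level is argued against: the 5th percentile of the medians of 10000 random lists of the same control level was -0.073, and the lowest of them was -0.28. A change in the macrophages themselves or in their number stays open and was not tested, and Slc40a1 of this list is also an erythroid gene.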
